A study of Mus musculus with 6 samples.

How the data were processed

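Total RNA from whole colon of 6 C57BL/6 mice was hybridised to Affymetrix mouse expression arrays, 1 array per mouse, with 3 Pparg-deficient (Lysozyme M Cre+) and 3 control (Cre-) littermates. The deposited values are log2 expression summaries, 1 per probe set and array. They were made by the authors with GCRMA, per the submitters' processing notes, a method that subtracts background modelled on probe sequence. Its version and settings, and whether all arrays were summarised together, are not given in the sources used here. The log2 scale was read from the deposited values, which run from 2.25 to 16.2 and are close in mean on all arrays. Unbound probe sets share a lowest value, so differences of genes near that floor are compressed and depend on the background model. The number of arrays, 3 per group, limits the precision.

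The table held 45101 probe sets, 64 of them Affymetrix controls. Gene names came from the platform annotation: 34958 probe sets named 1 gene, 932 named several and 9211 had none listed. The 34958 covered 18194 genes. For 34754 the Entrez identifier was in the reference gene table (GRCm38.p6), used for symbols and for which genes neighbour each other, and no symbol had to be changed. Probe sets that named several genes or none were left out of the gene comparison. A probe set was kept when it was above log2 4 on at least 3 of the 6 arrays, which left 19008 probe sets. Each gene was represented by its kept probe set with the highest mean over all arrays, giving 10491 genes. No further normalization was applied and no pseudocount was needed.

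Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), deficient minus control, with no covariate, and Benjamini-Hochberg adjustment over all genes. The threshold was an adjusted p under 0.05. Gene lists were tested with limma's camera (two-sided, preset inter-gene correlation 0.01) when at least 5 members were measured, with adjustment over the 29 lists tested. A member counted as measured when it was among the genes kept by the filter. In addition, p-values of members were adjusted over each list alone. The 35 lists held 660 gene names. They covered PPAR target genes, macrophage and monocyte markers, classical and alternative macrophage activation, pro-inflammatory cytokines, chemokines and their receptors, MHC class II and costimulation, leukocyte adhesion, interferon response and lysosome. Further lists were mitochondrial beta-oxidation, antimicrobial and acute-phase genes, matrix metalloproteinases, cell cycle, immediate-early and circadian genes, epithelial junctions, posterior Hox genes, and markers of immune, epithelial, mesenchymal, neural, adipose and endothelial cells. The tests, lists, alternatives and the rule for named genes were chosen before the data were examined.

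Named genes were Pparg and Lyz2. To these came 8 genes per direction among those past the threshold, with open places filled in order of unadjusted p by genes with p under 0.05, an absolute log2 difference of at least 1 and groups that did not overlap. Predicted transcripts and sex-chromosome genes were passed over. The 3 members with the smallest p were named for each list past the threshold, and 2 for each core list that was not. Uqcr10 and the genes that describe the tissue profile of the arrays were named after their values were seen. A list of Paneth cell markers was written after the data were examined and used only to describe the arrays.

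The procedure was tested on simulated data with 10491 genes and 3 arrays per group. Of 200 genes changed by a log2 of 1, 0% were recovered, by 2, 53.5%, and by 4, 89.5%, with 0, 8 and 15 false calls. All 20 simulated lists of 25 genes shifted by 1 had a camera p under 0.05, and 0 of 20 unshifted lists. Genes were simulated independently of each other, so this gives no rate of false calls for lists of correlated genes such as those measured.

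Alternatives changed 1 choice at a time. They were no filter and a filter at log2 6, quantile normalization and median centring, the mean of all probe sets of a gene, probe sets without cross-hybridisation suffixes, eBayes with trend and robust, array weights, a floor at log2 4, a replicate block, leaving out each array, an adjusted p under 0.1, every probe set on its own, camera with an estimated correlation, and fry. Added after the data were examined were a block for the 2 arrays with small intestine genes, leaving both out, sex read from Xist as a covariate (the same fit as without control replicate 2, so it is left out of counts of settings), every probe set on its own with a floor at log2 4, and the PPAR list without adipocyte genes.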

Results

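Gene expression was measured in the colon of mice with colitis caused by dextran sodium sulfate (DSS), a compound that damages the colonic epithelium. DSS was given at 2.5% and tissue was taken on day 7. In 3 mice the gene Pparg had been deleted in cells that express lysozyme M, mainly macrophages and neutrophils, by a Cre recombinase under that promoter (deficient samples). The other 3 were littermates with the same floxed gene and no Cre (control samples). Pparg encodes PPAR gamma, a nuclear receptor that drives fat storage genes and restrains inflammatory genes in macrophages. Each array held RNA from 1 mouse, and the replicates are labelled as biological ones. The comparison asked how expression in the inflamed colon differed when the receptor was lost in myeloid cells. Only the deficient mice carried Cre, which is inserted at the lysozyme gene Lyz2. Effects of Cre or of altered Lyz2 can therefore not be told apart from those of PPAR gamma loss. Every value is on a log2 scale, and all 6 animals had received DSS, so the response to DSS itself was not measured.

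The 6 arrays were alike in range but not in tissue profile. Between 41.4% and 42.7% of probe sets lay above log2 4 on each array, and array medians ran from 3.02 to 3.10. Control replicate 1 and deficient replicate 3 carried genes of the small intestine at high levels. Apoa1, an apolipoprotein of absorptive cells of the small intestine, stood at 15.46 and 15.23 on those 2 arrays and between 3.82 and 7.38 on the other 4. Fabp6, the ileal bile acid binding protein, stood at 15.32 and 14.49 there, against 5.72 to 7.81 elsewhere. Car1, a carbonic anhydrase of colonocytes, ran the other way at 2.83 and 7.02 against 13.60 to 15.32. Hoxa10, a gene of the posterior body axis, was at 2.87 and 3.89 on the 2 arrays and from 7.07 to 8.92 on the others. Of 10 small intestine enterocyte markers, 9 were higher on the 2 arrays, with a median difference of 4.21, while random lists of the same size matched on expression gave -0.41 to 0.28 (central 95% of 10000 lists). The 2 arrays were set apart because such genes were high on them, and random genes do not vary together as markers do. The range therefore describes the size of the difference and is no test. The first principal component held 54.7% of the variance and separated these 2 arrays from the other 4. Each genotype contained 1 of them, so list medians are given both without these arrays and between them for the lists that passed. All 6 samples are labelled as colon and are called so below, though these 2 did not share the profile of the other 4. Control replicate 2 alone expressed Xist, the transcript of the inactive X chromosome in females, at 12.11 against 2.27 on the others, and its Y-linked genes were near the floor.

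**Figure D1:**
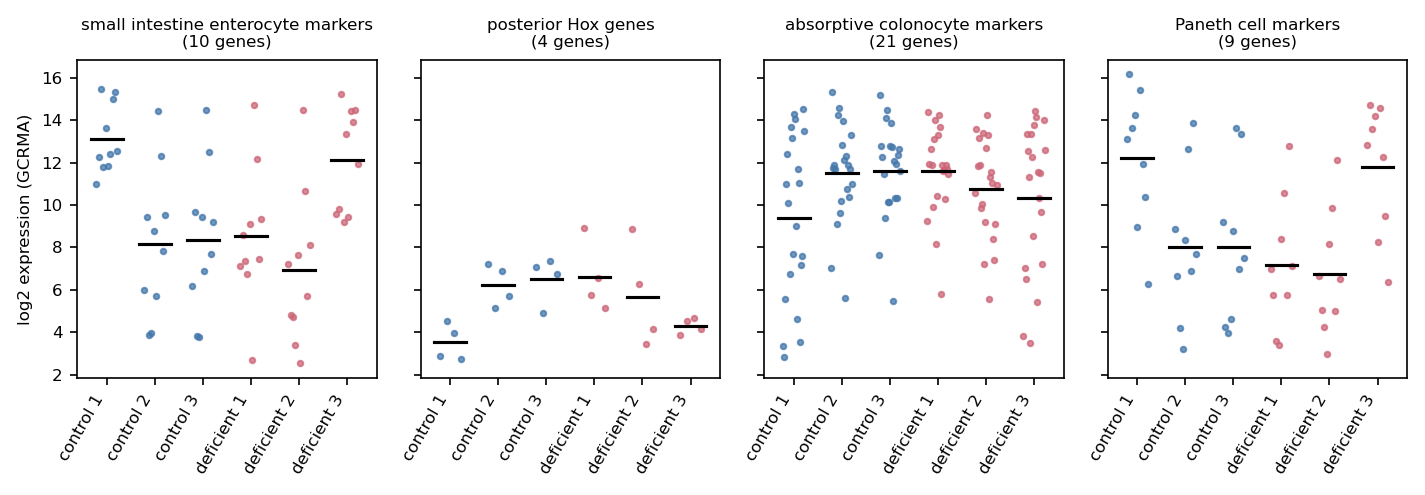
Log2 expression of the members of 4 gene lists on each of the 6 arrays, grouped by genotype, with the mean of each list as a bar. Control replicate 1 and deficient replicate 3 sit high for small intestine and Paneth cell markers and low for posterior Hox genes, with list means of 13.13 and 12.14 for small intestine markers against 6.93 to 8.54 on the other 4 arrays.

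Pparg itself was lower in the deficient colon by less than the spread within groups. Its single probe set (1420715_a_at) read 7.05 ± 2.53 (SD, n = 3) in deficient and 8.24 ± 2.57 (n = 3) in control samples, a log2 difference of -1.19 with a standard error of 1.73. The limma adjusted p with Benjamini-Hochberg correction was 0.880. Pparg followed the tissue profile, at 5.28 on control replicate 1 and 4.15 on deficient replicate 3 against 8.23 to 9.91 on the other arrays. Among the 4 arrays without small intestine genes the difference was -1.22 (limma unadjusted p 0.0116), with 8.77 and 8.23 in deficient against 9.91 and 9.54 in control samples. Between the 2 arrays with small intestine genes it was -1.13. Without deficient replicate 3 it turned to 0.26, in a fit where only a control array carried small intestine genes. The colon contains many Pparg-expressing epithelial cells that carry no Cre, and the position of the probes relative to the deleted exons is not known, so this value does not check the deletion. Lyz2, the lysozyme gene whose promoter drives Cre, was lower in every deficient sample than in any control sample. Its probe set (1423547_at) read 7.81 ± 2.25 against 12.10 ± 0.27 (SD, n = 3 each), a difference of -4.29 with a standard error of 1.09 and a limma adjusted p of 0.659. The 3 deficient arrays gave 6.80, 6.24 and 10.39, the last of them from the array with small intestine genes. Without the 2 arrays with small intestine genes the Lyz2 difference was -5.47, and between them it was -1.93. Since Cre is inserted at Lyz2, its level cannot be read as an effect of PPAR gamma loss or of fewer myeloid cells.

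No single gene among 10491 passed the limma test at an adjusted p under 0.05, and the smallest adjusted p was 0.536. At an unadjusted p under 0.05 there were 783 genes, 535 higher and 248 lower in deficient samples, where 524.55 were expected by chance. At a p under 0.01 there were 131, with 86 higher, against 104.91 expected. Groups did not overlap for 1417 genes, or 13.5%, where chance gives 10%. The genes described next therefore have the smallest unadjusted p among those with separate groups and an absolute log2 difference of at least 1. Their differences are values rather than calls. When each probe set was tested on its own, 1 of them passed: 1434340_at of Uqcr10, a subunit of respiratory complex III, at 8.77 ± 0.46 in deficient and 2.69 ± 0.07 in control samples. Its log2 difference was 6.08 with a limma adjusted p of 0.00978 (4.77 and 0.0345 with values under 4 set to 4, since the control level is at the floor), while the brightest Uqcr10 probe set (1424364_a_at) differed by -0.16. Uqcr10 is named here because of its values.

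The 8 genes chosen as higher in deficient colon came from different functions. Ifit2, an interferon-induced antiviral gene (1418293_at), was at 9.18 ± 0.50 against 6.69 ± 0.39, a difference of 2.50. Pla2g5, a secreted phospholipase (1417814_at), was higher by 2.60 at 7.84 ± 0.58 against 5.24 ± 0.26. Gch1, which makes the cofactor of nitric oxide synthase, was higher by 1.63, and Tgm2, a transglutaminase, by 1.06. Mfsd2a, a lipid transporter, was higher by 2.29. Bhmt2, a methyltransferase, was higher by 2.28 and Vav1, a signalling protein of blood cells, by 1.56, both from control levels near the floor of the arrays. With values under 4 set to 4, Bhmt2 still differed by 2.21. Vav1 lay at 2.61 to 3.62 in controls with a deficient mean of 4.68, so most of its difference was under log2 4. Rps6 was higher by 1.70 on 1 probe set (1416142_at), but probe sets that name it together with a pseudogene ranged only from -0.12 to 0.19, so that value is uncertain. The 8 genes had limma adjusted p from 0.536 to 0.659. Each was higher on all 3 deficient arrays than on any control array, which the naming rule required.

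The 8 genes chosen as lower in deficient colon were also of mixed function. Acaa1b, a peroxisomal thiolase and PPAR target (1424451_at), showed the largest difference of the set at -5.36, from 8.38 ± 1.78 in control to 3.03 ± 0.70 in deficient samples. Abhd1 differed by -4.80, from 8.39 ± 0.75 to 3.59 ± 1.10, and the deficient levels of both lay near the floor. Slc30a10, a manganese exporter, was lower at -3.01. Sgk1, a kinase induced by glucocorticoids and aldosterone that promotes sodium uptake, differed by -1.90, and Bambi, an inhibitor of TGF beta signalling, by -1.56. Neu1, the lysosomal sialidase, differed by -1.51, Galnt11, a glycosyltransferase, by -1.07, and Npas2, a clock transcription factor, by -1.02. For all 8 the groups did not overlap, which the naming rule required, and limma adjusted p ran from 0.536 to 0.659.

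**Figure D2:**
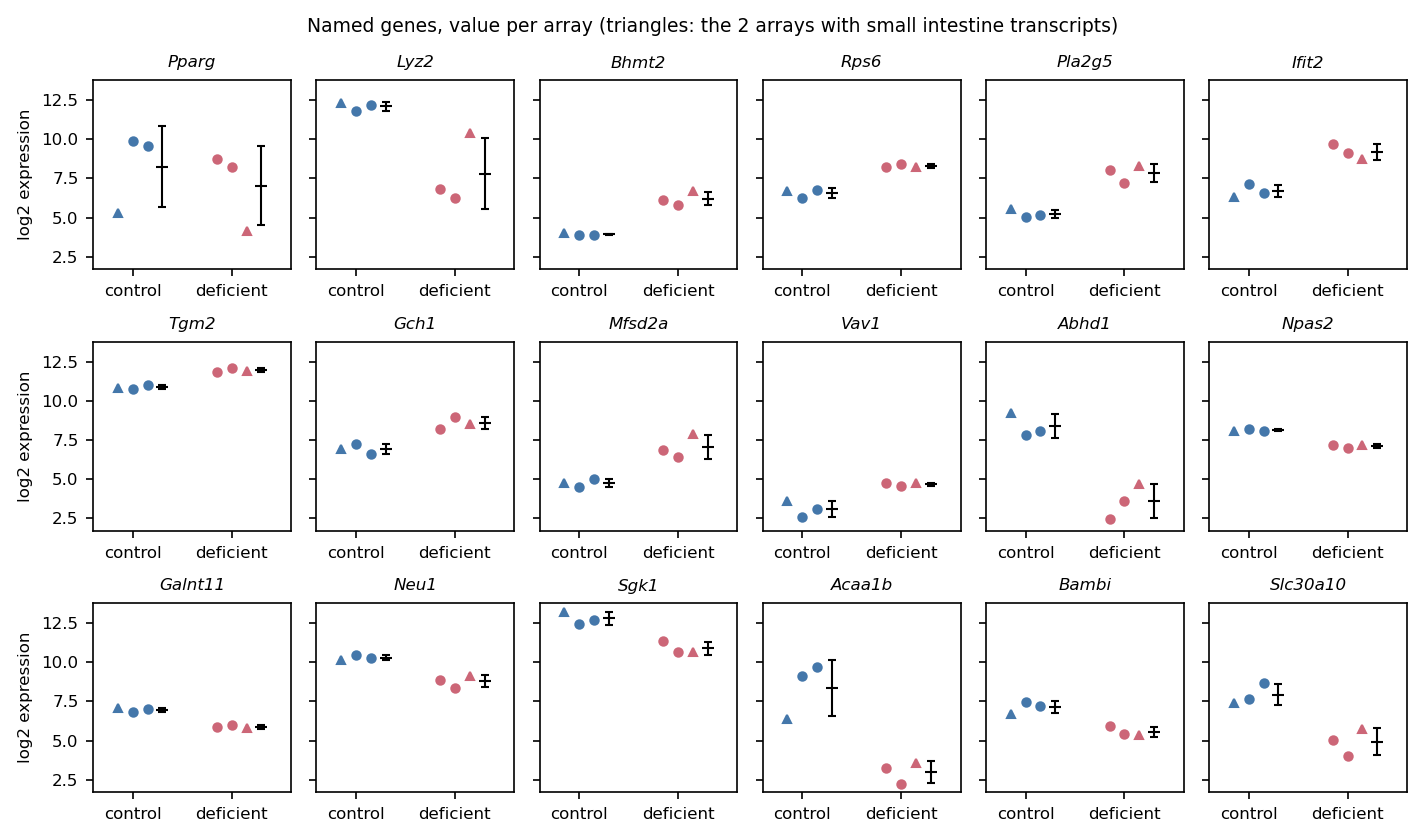
Log2 expression of 18 genes on each array, with control and deficient samples side by side, bars for the mean and SD of 3 arrays, and triangles for the 2 arrays with small intestine genes. Lyz2 and Acaa1b lie lower in deficient samples, at means of 7.81 and 3.03 against 12.10 and 8.38, while Pparg varies more within groups than between them.

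Gene lists were tested as groups, since no single gene could be called. With limma's camera test at a preset correlation of 0.01, 15 of 29 lists passed a Benjamini-Hochberg adjusted p under 0.05, 9 of them higher and 6 lower in deficient colon, while splits of the 6 arrays that mix the genotypes gave up to 16. With a correlation estimated from the data none did, and the smallest adjusted p was 0.299. By fry, which asks whether a list's genes move one way on balance, none did either, and its smallest adjusted p was 0.196. No list member passed over all genes tested, while 8 lists had at least 1 member that passed when adjusted over the list alone.

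Macrophage and monocyte markers shifted higher. Of 21 measured members 19 were higher, with a median log2 difference of 1.19, and 9 passed when adjusted over the list alone against 0 over all genes. The 2 lower members were Mertk at -0.77 and Cx3cr1 at -0.31, and Adgre1 was higher by only 0.24. Each of these had an unadjusted limma p above 0.05. Msr1, the macrophage scavenger receptor, was at 7.44 ± 0.93 against 5.24 ± 0.36. Aif1, a marker of activated macrophages, was higher by 1.50, and Ly86, a partner of a Toll-like receptor homologue, by 1.20. Camera gave an adjusted p of 8.9e-09, and the adjusted p was 0.299 with an estimated correlation. The median was 1.29 without the 2 arrays with small intestine genes and 0.80 between them.

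Genes of classical macrophage activation shifted higher as well, with all 6 measured members (of 16 listed) higher and a median difference of 2.56. Ptgs2, the inducible cyclooxygenase, was higher by 3.64, the cytokine signalling inhibitor Socs3 by 2.30 and the formyl peptide receptor Fpr2 by 2.26. Without deficient replicate 2, Fpr2 was higher by 1.36. Ptgs2 was at 11.81 on that array against 8.37 and 6.17 on the other deficient arrays. The camera adjusted p was 0.00189, and the adjusted p was 0.308 with an estimated correlation. Only 1 member passed adjusted over the list alone, and 0 over all genes. The 5 measured neutrophil markers (of 20 listed) were all higher, with a median of 3.33 and none passing adjusted over the list alone. They include Fpr2, shared with the classical activation list, and Mmp9, shared with the metalloproteinase list. S100a9, a subunit of calprotectin, stood at 9.73 ± 2.62 against 5.08 ± 2.86, with Il1r2, a decoy receptor for interleukin 1, higher by 3.33 from a control level near the floor (2.80 with values under 4 set to 4). Camera gave an adjusted p of 0.00189, and the adjusted p was 0.299 with an estimated correlation. Medians of both lists were larger among the 4 arrays without small intestine genes, at 3.56 and 4.36, than between the 2 arrays with them, at 0.49 and 1.27. In fits without 1 array the neutrophil median ran from 2.09 to 4.46. The other genes of both lists had no single-gene probe set past the filter. A gene under log2 4 on all 3 control arrays, such as Il1r2, was kept only if all 3 deficient arrays lay above 4. Such members could only be higher.

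Chemokines and their receptors were higher for 18 of 21 members, with a median of 1.32. Cxcl9 and Cxcl10, interferon-induced attractants of T cells, were higher by 3.90 and 2.77, and the receptor Ccr1 by 1.57. The camera adjusted p was 2.22e-05, the adjusted p was 0.299 with an estimated correlation, and 3 members passed adjusted over the list alone. Its median was 1.86 without the 2 arrays with small intestine genes and 0.54 between them. Pro-inflammatory cytokines had a median of 2.34 over 6 members but did not pass, with a camera adjusted p of 0.0511. Of the 6, Il1b and Il6 are also in the classical activation list. The list passed in 11 of 19 alternative settings. Its median ran from 1.30 to 3.64 in fits without 1 array and was 0.94 with no filter on low values, which lets in more members, 3.39 without the 2 arrays with small intestine genes and 0.03 between them. In that list Il18 was higher by 1.23 and Il33 by 1.85, each an alarm cytokine of barrier cells. The groups overlapped for Il33, which differed by 2.75 without the 2 arrays with small intestine genes and by 0.05 between them. Interferon response genes were higher for 21 of 24 members, with a median of 0.75, led by Ifit2, Cxcl10 and Cxcl9. Cxcl9 and Cxcl10 are also in the chemokine list, so these lists are not fully separate results. Their camera adjusted p was 1.18e-06, the adjusted p was 0.425 with an estimated correlation, and 7 members passed adjusted over the list alone. The interferon median was 1.48 without the 2 arrays with small intestine genes and -0.15 between them, and ran from 0.48 to 1.46 in fits without 1 array.

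Leukocyte adhesion genes were higher for all 9 members, with a median of 0.997. Icam1, which captures leukocytes on endothelium, was higher by 1.39, its integrin partner Itgb2 by 1.35 and the selectin ligand Selplg by 1.48. Between the 2 arrays with small intestine genes Icam1 differed by 0.48, Itgb2 by 0.05 and Selplg by -0.70. Each was highest on deficient replicate 2. Camera gave an adjusted p of 0.00849, the adjusted p was 0.508 with an estimated correlation, and the call ended without deficient replicate 2. The median was 1.60 without the 2 arrays with small intestine genes and -0.34 between them. Matrix metalloproteinases and their inhibitors were higher for 12 of 14 members, with a median of 1.22, and Mmp10, Mmp13 and Mmp12 were higher by 4.08, 3.88 and 2.06. That median was 1.65 without the 2 arrays with small intestine genes and 0.46 between them, where Mmp10 differed by 6.10 and 0.06. Their camera adjusted p was 0.00226, the adjusted p was 0.443 with an estimated correlation, and the call ended without control replicate 1. MHC class II and costimulation genes did not pass, with a median of 0.64 and a camera adjusted p of 0.0928, though they passed in 7 of 20 alternative settings. H2-DMb2, a peptide-loading subunit, was higher by 1.02 on a probe set prone to cross-hybridisation (1443687_x_at) but by 0.0728 on one without such a suffix, so that value is uncertain, and Cd274, the checkpoint ligand PD-L1, by 1.07, though by 0.68 without deficient replicate 2 and by -0.17 between the 2 arrays with small intestine genes. The median of this list was 1.45 without the 2 arrays with small intestine genes and -1.31 between them. Genes of alternative macrophage activation had a median of 0.43 and a camera adjusted p of 0.376, with Il4ra, the interleukin 4 receptor, higher by 0.63 and Socs2 at -1.08.

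Cell cycle genes were higher for 28 of 28 measured members, with a median difference of 1.08. The proliferation marker Mki67 was at 10.33 ± 0.62 against 8.97 ± 0.18, the replication helicase subunit Mcm2 was higher by 0.89 and the topoisomerase Top2a by 1.30. The camera adjusted p was 1.51e-14, and the adjusted p was 0.299 with an estimated correlation. None passed adjusted over the list alone. The median was 1.38 without the 2 arrays with small intestine genes and 0.39 between them. Immediate-early genes were higher for 11 of 14 members with a median of 0.71, among them Egr1 by 1.67, Junb by 1.19 and Fos by 0.65. Their camera adjusted p was 0.0204, the adjusted p was 0.443 with an estimated correlation, and the call ended without control replicate 1 or deficient replicate 2, without both arrays with small intestine genes, with a filter at log2 6 and with array weights. Their median was 0.66 without the 2 arrays with small intestine genes and 0.69 between them.

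PPAR target genes shifted lower in the deficient colon, with 19 of 24 members lower and a median of -0.84. The 5 higher members were Apoe by 0.85, Abcg1 by 0.60, Nr1h3 by 0.40, Abca1 by 0.32 and Scarb1 by 0.14. Each of these had an unadjusted limma p above 0.05. Besides Acaa1b, Pck1, which commits carbon to glucose and glyceride synthesis, went from 9.23 ± 0.40 in control to 6.21 ± 1.22 in deficient samples. Ehhadh, the peroxisomal bifunctional enzyme, differed by -1.74. Camera gave an adjusted p of 4.67e-09, the adjusted p was 0.299 with an estimated correlation, and 3 members passed adjusted over the list alone. The median was -0.90 without the 2 arrays with small intestine genes and -0.45 between them. Adipocyte markers were lower for all 9 members with a median of -1.34, and 2 of them, Fabp4 and Cidec, are also in the PPAR list. Adipoq, the hormone adiponectin, was at 8.78 ± 0.64 against 10.52 ± 0.62, the lipogenic regulator Thrsp differed by -4.25 and the fatty acid carrier Fabp4 by -0.97. The camera adjusted p was 8.9e-09, the adjusted p was 0.299 with an estimated correlation, and 5 members passed adjusted over the list alone. The adipocyte median was -1.96 without the 2 arrays with small intestine genes and -0.72 between them. Mitochondrial beta-oxidation genes were lower for 19 of 19 members by a small median of -0.31, and 6 of the 19, Acadm and Acaa2 among them, are also in the PPAR list, so the 2 lists are not separate results. The members with the smallest p were Acadm at -0.73, Acaa2 at -1.47 and Hadh at -0.61. Hadh was read on a probe set prone to cross-hybridisation (1455972_x_at). It lay lowest on deficient replicate 2, at 13.02 against 13.66 and 13.93 on the other deficient arrays. Camera gave an adjusted p of 2.01e-06, and the adjusted p was 0.299 with an estimated correlation. Their median was -0.49 without the 2 arrays and -0.08 between them, and ran from -0.52 to -0.19 in fits without 1 array.

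**Figure D3:**
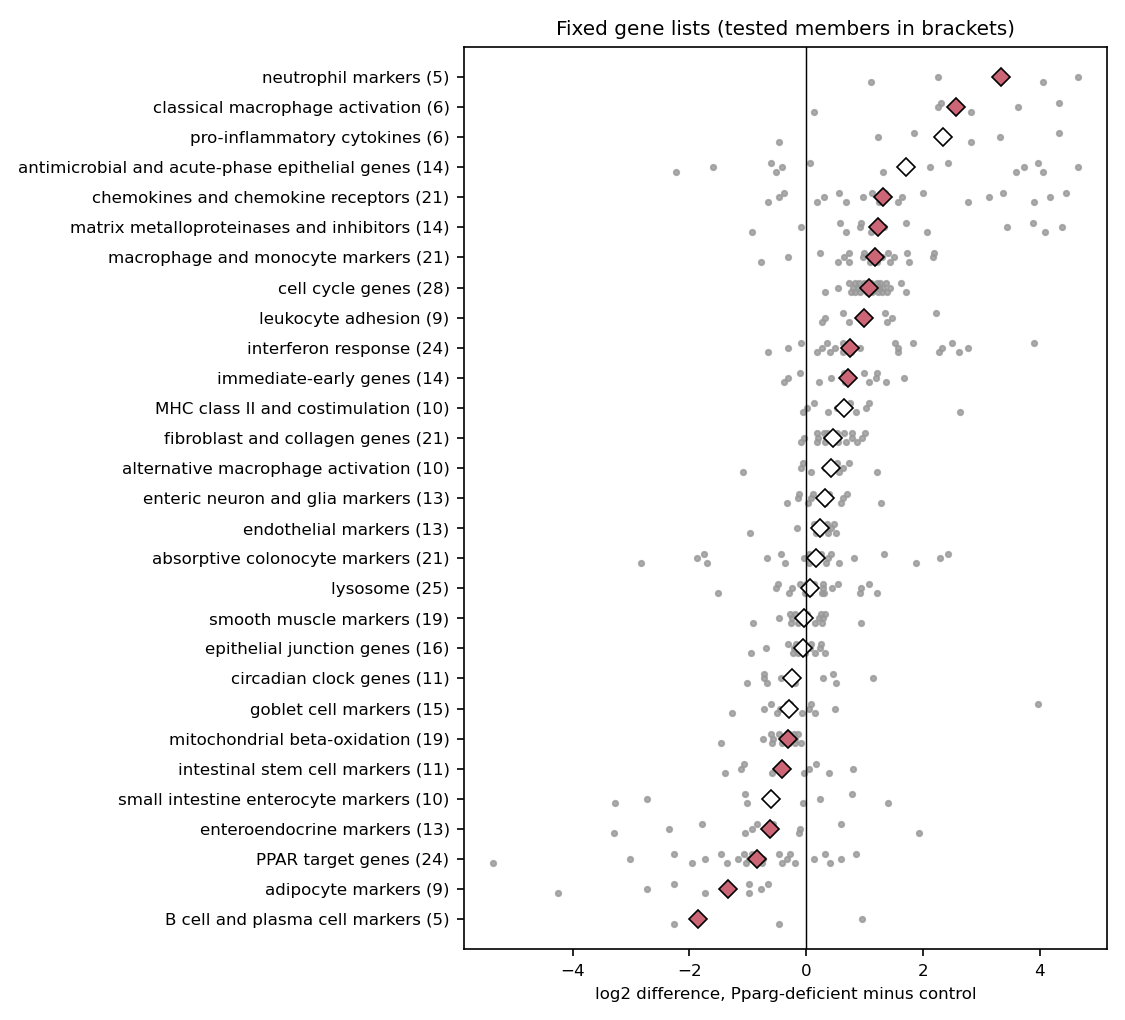
Log2 differences, deficient minus control, of the members of the 29 tested lists as grey points, with the median as a diamond that is filled where the camera adjusted p was under 0.05. Neutrophil markers and classical macrophage activation lie farthest to the higher side, at medians of 3.33 and 2.56, and adipocyte markers lie to the lower side at -1.34.

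Enteroendocrine, B cell and stem cell lists shifted lower. Enteroendocrine markers were lower for 11 of 13 members with a median of -0.62, including the hormone somatostatin (Sst) at -0.92, the calcium sensor Scgn at -0.62 and the granule protein Chga at -1.78. The camera adjusted p was 0.000888, and the adjusted p was 0.299 with an estimated correlation. Their median was -1.09 without the 2 arrays with small intestine genes and -0.18 between them, and ran from -1.02 to -0.52 in fits without 1 array. B cell and plasma cell markers were lower for 4 of 5 members with a median of -1.85. The antibody joining chain Jchain differed by -2.26, the IgA heavy chain Igha by -1.85 and Mzb1 by -1.89, each with overlapping groups. Their camera adjusted p was 0.0297, and the adjusted p was 0.299 with an estimated correlation. Without the 2 arrays with small intestine genes the median was -0.78 and the call ended (camera adjusted p 0.224), and between them it was -2.83. The call also ended with those arrays as a block (0.0979) and with array weights, where the median was -0.16 (0.357). With no filter on low values, which lets in more members, it passed at a median of only -0.21. Intestinal stem cell markers were lower for 7 of 11 members with a median of -0.41, with Tnfrsf19 at -1.39, Lgr5 at -1.11 and Rnf43 at -0.58. Their camera adjusted p was 0.0379, and the adjusted p was 0.299 with an estimated correlation. The stem cell median was -0.70 without the 2 arrays and -0.01 between them. The B cell call was kept in 3 of 6 fits that left out 1 array, and the stem cell call in 2 of 6. The stem cell call also ended with a filter at log2 6, quantile normalization and array weights. No member of the enteroendocrine, B cell, stem cell, beta-oxidation, adhesion, metalloproteinase or immediate-early lists passed adjusted over the list alone.

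Lists of other cell types of the colon wall did not pass camera as planned. Smooth muscle markers had a median of -0.03 (adjusted p 0.334), endothelial markers 0.23 (0.523), enteric neuron and glia markers 0.33 (0.265) and fibroblast and collagen genes 0.47 (0.0552). The fibroblast list passed, higher, in 11 of 20 alternative settings and turned direction in 3. Smooth muscle, goblet cell, circadian clock and small intestine enterocyte lists passed, lower, in 2 of 20 settings each, and neuron and glia markers and genes of alternative macrophage activation, higher, in 1 of 20 each. Absorptive colonocyte markers had a median of 0.16 (camera adjusted p 0.903), goblet cell markers -0.29 (0.227), epithelial junction genes -0.05 (0.376) and small intestine enterocyte markers -0.61 (0.227). Antimicrobial and acute-phase epithelial genes had a median of 1.71 but went both ways, with 9 of 14 higher and a camera adjusted p of 0.233. Lysosome genes had a median of 0.07 (camera adjusted p 0.761) and circadian clock genes -0.24 (0.0803). Too few members were measured to test T cell (3), regulatory T cell (2), mast cell (1), erythrocyte (1), squamous epithelium (4) and posterior Hox (4) lists.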

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

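The fits with a block for the 2 arrays with small intestine genes, with both left out, with sex as a covariate, with every probe set on its own under a floor at log2 4 and with the PPAR list without adipocyte genes were chosen only after the data were seen. The count of 0 genes at a limma adjusted p under 0.05 (783 at an unadjusted p under 0.05) became 2 with array weights, Bhmt2 and Pla2g5, in a fit that gave deficient replicate 1 a weight of 7.25, and 1 with every probe set on its own, with or without a floor at log2 4. At an adjusted p under 0.1 it stayed 0. The count at an unadjusted p under 0.01, 131, became 204 with no filter and 767 with array weights, and that under 0.05 became 2132 with array weights. With the small intestine block they were 346 and 1411, with both arrays left out 371 and 1461, and with sex as a covariate 56 and 435. Only control replicate 2 differed in sex, so that fit equals the one without it in all 97 results, says nothing about sex and is not counted as a setting. Leaving out 1 array gave 56 to 308 and 431 to 1191. The count under 0.05 was 435 without control replicate 2, 482 without control replicate 3, 431 without deficient replicate 2 and 1191 without control replicate 1. Without deficient replicate 3 there were 760 genes higher and 290 lower, and without deficient replicate 1 there were 341 and 238. The count thus rose above 783 only where an array with small intestine genes was left out, and the cause was not tested. Same-numbered deviations from the group means correlated at -0.54, 0.36 and -0.61, and the best partner of each control had another number. These values carry the tissue profile of the 2 arrays with small intestine genes, so they do not exclude a pairing by replicate number. As a replicate block the replicate numbers gave 70 and 437 genes and left the 15 list calls in place. Of the genes at p under 0.05, 535 were higher and 248 lower, or 68.3% higher. After quantile normalization the split was 427 to 301 (58.7%), and after median centring 410 to 301 (57.7%).

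The 15 lists past the threshold became 0 with camera's estimated correlation and 0 with fry. In the other settings 10 to 15 of the called lists were kept and none turned direction, with 3 left untested by the filter at 6. Other lists came to pass, up to 5 in 1 setting (20 lists past with no filter, 19 without deficient replicate 3), most often fibroblast genes (11 of 20 settings) and pro-inflammatory cytokines (11 of 19). Leaving out 1 array ended the leukocyte adhesion call (deficient replicate 2), the metalloproteinase call (control replicate 1), the immediate-early call (either of those 2), the B cell call (either of those 2, or deficient replicate 3) and the stem cell call (each array but deficient replicates 1 and 3). Their medians ran from 0.39 to 1.81, 0.60 to 1.86, 0.44 to 0.98, -2.19 to -0.73 and -0.62 to -0.21. Array weights ended the last 3 of these calls too, and some other settings ended 1 or 2 of them. The macrophage median ran from 0.82 to 1.43 and the cell cycle median from 0.83 to 1.32, both called in 6 of 6. Of 1123 values of 63 named genes under 18 settings, 1120 kept direction and side, 2 came to pass and 1 reversed, Igha with array weights at 0.0403. The log2 difference of Pparg ran from -2.67 to 0.26 over the 6 fits. It was positive only without deficient replicate 3, where only a control array carried small intestine genes. The camera direction of lists not past the threshold also turned in some fits, and the cause was not tested. Their medians in those fits were, with array weights, 0.0475 for endothelial, -0.0365 for neuron and glia, 0.22 for fibroblast and 0.00293 for lysosome lists. The colonocyte list gave 0.10 with the filter at 6, 0.16 with the small intestine block and -0.35 with both arrays left out, the lysosome list 0.0567 on probe sets without suffixes, and the smooth muscle list 0.19 with sex as a covariate. Over fits without 1 array, ranges were -0.50 to 0.45 for colonocyte, -0.0627 to 0.50 for endothelial, -0.0778 to 0.68 for neuron and glia, -0.0887 to 0.0421 for junction, 0.0412 to 0.84 for fibroblast, -0.0946 to 0.42 for lysosome, -1.78 to 0.67 for small intestine and -0.35 to 0.19 for smooth muscle lists. Signal near the floor limits Acaa1b and Abhd1, whose differences were -4.38 and -4.16 with values under 4 set to 4. It limits Vav1 more, since all its control values lay under 4 and its deficient mean was 4.68.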

Other observations

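The tests on the small intestine genes, the PPAR targets and the adipocyte list, and those on Uqcr10 and switching probe sets, were chosen only after the results were seen, as were the genes of this first paragraph. Antimicrobial and acute-phase genes went both ways with wide errors, and none passed the limma test. Retnlb, an antimicrobial goblet cell product, was higher by 3.97 (SE 2.78) in deficient samples. Lcn2, an iron-scavenging protein, was higher by 3.59 (SE 1.27) and Saa3, an acute-phase protein, by 3.73 (SE 1.71). Lyz1, Ang4 and Reg3b differed by -2.24 (SE 1.39), -1.59 (SE 2.01) and -0.60 (SE 0.77). Lyz1 was read on a probe set prone to cross-hybridisation. The Lyz1 probe set without such a suffix differed by 0.45 but lay near the floor, at 3.57 in deficient against 3.11 in control samples. The Lyz1 value is therefore uncertain. The stromal protease Mmp3 was higher by 4.37 (SE 2.16), its inhibitor Timp1 by 3.45 (SE 1.78), and the cytokines Il6 and Il11 by 4.33 (SE 2.33) and 3.32 (SE 1.81). Within the interferon list, Irf7, a regulator of type I interferon, went the other way at -0.66, while the guanylate-binding protein Gbp2 and the interferon-gamma-induced GTPase Iigp1 were higher by 2.27 and 2.62. Among clock genes, Nfil3, a repressor, was higher by 1.15 and Npas2 and Tef differed by -1.02 and -0.72, and 2 of the 11 passed limma when adjusted over the list alone. The mean difference of macrophage markers exceeded that of smooth muscle markers by 1.06 (SE 0.181 over genes, which are not independent replicates), of endothelial markers by 0.872 (SE 0.192), of neuron and glia markers by 0.744 (SE 0.199) and of fibroblast genes by 0.568 (SE 0.172).

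Small intestine genes on control replicate 1 and deficient replicate 3 may come from small intestinal tissue in those samples, since markers written before the data were examined differed by a median of 4.21 between these 2 arrays and the other 4, and the abundant Apoa1 and Fabp6 stood above 14 on both. A share of small intestine added to colon like that of the other 4 samples is argued against by 7 genes that were above log2 10 on those 4 and at least 3 lower on both arrays, Car1 at 2.83 and 7.02 among them, where other pairs of arrays gave at most 1 (over the 6 pairs of bounds tried before these were chosen, 2 to 10 genes, and at most 2 for other pairs). Degraded RNA is argued against by beta-actin, whose larger 3' minus 5' difference on the 2 arrays was 0.855, below the 1.07 of control replicate 3. A swap of these 2 labels between genotypes is argued against by Lyz2, which differed by -1.93 between them in the direction of the other arrays. Paneth cell markers, listed after the data were examined, differed by a median of 5.05, with 7 of 9 higher on these 2 arrays. Small intestine alone, with under an eighth of such colon or with colon of another kind stays open, as does another part of the gut. No biological explanation was tested.

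The lower PPAR target list may in part reflect less fat attached to the deficient samples, a candidate source that the adipocyte list, with a median of -1.34 and Fabp4 as its brightest named member at 12.07 against 13.04, could supply. For the PPAR targets outside the adipocyte list, with a median of -0.74, fat and other causes cannot be told apart, because 9 of those 22 genes, among them Pck1, Cd36 and Lpl, are expressed by fat cells too. The 9 had a median of -1.03 and the others -0.47. The gut segment of the 2 arrays with small intestine genes is argued against as the whole cause, since without them the median was -0.90. The loss of PPAR gamma in myeloid cells, Cre or lower Lyz2, more severe epithelial injury and lower food intake stay open and untested.

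Uqcr10 gave the only probe set past the limma test when every probe set was tested, and it disagreed with the gene's brightest probe set. In deficient samples 1434340_at was at 8.77 ± 0.46 and 1434341_x_at at 9.83 ± 0.59, against 2.69 ± 0.07, at the floor, and 6.37 ± 0.68 in controls (SD, n = 3), and with values under 4 set to 4 the first still differed by 4.77. A change of the whole transcript is argued against, since 1424364_a_at differed by -0.16 at 11.64 against 11.80. DNA of another strain carried along with the Cre insertion at Lyz2 is argued against as well, since 0 of the 3 probe sets that switched in this way (groups at least 2 apart while the brightest other probe set of the gene differed by under 0.5) belonged to the 100 genes nearest to Lyz2. Of these 3, 2 are the Uqcr10 probe sets themselves and the third was 1452535_at of Ighm. The count therefore mainly restates where Uqcr10 lies and is no independent test. A sequence difference elsewhere in the genome, another transcript end and binding of another transcript may each account for the Uqcr10 values and stay open.

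The 6 arrays can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 0 genes at a limma adjusted p under 0.05, where the highest other gave 1 (all 10 are as large as 0, so this count says nothing about chance), and 783 genes at an unadjusted p under 0.05, where the highest other gave 1130 (5 of 10). It gave 15 camera lists, where the highest other gave 16 (3 of 10), and 3 switching probe sets, where the highest other gave 0 (1 of 10). The rule for switching was written after the Uqcr10 values of the real split were seen, and 2 of the 3 are Uqcr10 probe sets. That count therefore favours the real split in advance and says nothing about chance. The 4 splits that set control replicate 1 and deficient replicate 3 on the same side gave 864 to 1130 genes at an unadjusted p under 0.05, all above the real split.

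Among 1953 probe sets with no single gene name, 1445226_at, with no gene listed, was lower at 4.06 ± 0.11 in deficient against 7.55 ± 0.51 in control samples, a log2 difference of -3.49 with a limma adjusted p of 0.0499 over those probe sets. It was 1 of 1953 past the threshold.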
